A study of Homo sapiens with 6 samples.

How the data were processed

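Gene expression was measured in cultured stromal fibroblasts isolated from ovarian endometriomas (endometriosis cysts of the ovary). Per the labels' protocols, cells from 3 patients were transfected at about 70% confluence with 60 nM of a non-targeting siRNA or of an siRNA against NR5A1, and harvested after 48 h. NR5A1 encodes steroidogenic factor 1, abbreviated SF1 in the sample names; SF1 is also the official symbol of an unrelated gene, splicing factor 1. Each group had 3 samples, numbered 1 to 3.

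Per the file headers, each sample was hybridised to 1 Agilent expression array, read in 1 scan channel (the labels give Cy3 for every sample but cite a 2-colour labelling protocol), and quantified with Agilent Feature Extraction version 11.0.1.1, which subtracted the background and detrended each spot's intensity within the array. These deposited intensity values were not scaled between arrays. The deposited spot flags, another output per the file headers, state whether a spot was well above background, saturated or an outlier. A deposited value table of the whole series also holds intensity values on a linear scale; how the authors made it is not given in the sources used here. Its column medians lay between 25.2 and 26.1. In that table the mean log2 value of the 2 samples that share a number was the same for all 3 numbers, to within 1.19e-09, so differences between the numbers had been removed. Its differences between the siRNAs ran in the same direction as those of the scanner values (correlation across genes 0.857, 0.861 and 0.718 in pairs 1, 2 and 3; genes are not independent replicates). Scale, centring and direction of the table were thus read from the values. The table was used as an alternative.

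From the scanner files, log2 of the processed signal minus each array's 75th percentile over non-control spots was computed. Of 62976 spots per array, 58717 were not controls and represented 50599 probes. Outlier spots were left out, spots of a probe were averaged, 98 probes without a usable spot on some array were dropped, and 102 probes for XIST, TSIX or chromosome Y were left out of every step. Accessions in the files were matched without versions to NCBI RefSeq (GRCh38.p14) for names: 28025 of the 50399 remaining probes had 1 symbol, 0 had several and 22374 had none and kept the file's name. The array design is on hg19, and no coordinates were used. Probes well above background on all arrays of at least 1 group were kept, and the brightest probe stood for its gene, which left 17296 features, 13272 of them with a symbol.

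Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg over all features). NR5A1 was also tested without the filter on dim probes and with an exact permutation test, whose smallest possible p with 3 against 3 is 0.10. A set of 27 gene lists, fixed before the data were examined, was tested with camera at its preset correlation of 0.01, adjusted over the lists. Where a gene was not well above background on any array of a group, its fold is a bound: the bright group's mean against, per dim array, the higher of the gene's own signal and the lowest signal among probes well above background. Such a bound is for the group means of the processed signal. It leaves out the spread between samples, and other background corrections or sources can give smaller folds. Named genes followed a rule fixed at the same time: NR5A1 and SF1; 12 genes in each direction past adjusted p 0.05, with places left filled by the smallest unadjusted p among genes at least 1.5-fold different and of the same sign in all 3 same-numbered differences; the same for the fit with the replicate number as a block; and the 4 members of each list with the smallest unadjusted p. Genes outside this rule are identified as such.

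The numbers pair the samples. Deviations from the group mean correlated at 0.756, 0.822 and 0.619 between same-numbered samples over the features tested. The correlations were below 0 for each differently numbered combination. Deviations within a group sum to 0, so positive same-numbered values push these down, and they add little evidence. Over the 19456 spots brighter than 50 on all arrays the same-numbered values were 0.900, 0.917 and 0.852. The labels state 3 patients but not that a number marks a patient, so the pairing comes from the values. The replicate number accounted for 80.3% of the variance and the siRNA for 6.38%. The main test has no replicate block, as fixed in advance.

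All 6 arrays lay on 1 slide with 1 scan, so neither could be fitted as a batch. The 75th percentile of the signal ran from 149 to 224, and no spot was saturated. The procedure was then tested on simulated data with 17296 features and the real spreads. Changes of every size were placed in the same simulated data, and the adjustment eases as more features pass. The shares called hold for that number of changes and may be lower where fewer genes change. The fit without a block called 13 of 67 changed by 1 on the log2 scale, 46 of 67 changed by 2 and 54 of 66 changed by 3, and 0 unchanged ones; with the replicate block, 139 changed and 9 unchanged features were called. A simulated list shifted by 0.3 was called and 0 of 26 unshifted lists were; these simulated genes were independent of each other, unlike real ones. Alternatives covered background correction, scaling, filters, probe choice, moderation, array weights, the value table, the replicate block, left-out samples and the list test. Figures were drawn with matplotlib 3.10.9.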

Results

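In endometriotic stromal fibroblasts given siRNA against steroidogenic factor 1, its gene NR5A1 was at least 6.31-fold lower by the processed signal. STAR, which carries cholesterol into mitochondria for steroid synthesis, was 13.5-fold lower (log2 difference -3.75 ± 0.68, SE of the fit without a block, n = 3 each). Genes of DNA replication and mitosis had a median log2 difference of 0.33, against 0.13 with median scaling. SLC40A1, the cellular iron exporter, was 2.60-fold lower. No single gene passed the adjusted threshold, and 0 gene lists did when camera estimated the correlation between genes. Levels are log2 signal relative to the array's 75th percentile, and differences are SF1 siRNA minus non-targeting siRNA. Between 49.1% and 52.8% of spots were well above background on 5 arrays and 60.3% on that of SF1 siRNA replicate 3.

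NR5A1, the targeted gene (probe A_23_P216915), was lower in all 3 samples given its siRNA. Its processed signal was 102, 50.5 and 85.9 in the non-targeting samples 1, 2 and 3 and 8.32, 7.58 and 5.01 in the SF1 siRNA samples. It was well above background on all 3 non-targeting arrays and on 0 of the SF1 siRNA arrays. By this signal the level was therefore at least 6.31-fold lower, with measured means of -1.31 ± 0.59 and -4.78 ± 0.11 (SD, n = 3 each). With samples exchanged freely between the groups, ignoring the pairing, the exact permutation p was 0.10, the smallest possible with 3 against 3. Exchanges within the 3 pairs alone could give no p under 0.25. The unadjusted limma p, also without the pairing, was 7.43e-05 without the filter on dim probes. Over all features tested its limma adjusted p was 0.577. SF1, the splicing factor gene whose symbol the siRNA's name shares, differed by 0.07 ± 0.25 (SE).

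No gene passed limma's adjusted p of 0.05 (0 of 17296 features). At an unadjusted p under 0.05 there were 148 features, and 96 of them differed at least 1.5-fold, 60 higher and 36 lower. With the replicate number as a block 0 features passed after adjustment, 1279 were under the unadjusted threshold and 236 of these differed at least 1.5-fold. Chance at 5% would give 865 features without any pairing. Of unchanged simulated features, drawn with the pairing, 1.22% were under the threshold without the block and 5.81% with it. The direction split depended on scaling: 62.5% of the 96 were higher, against 31.8% with quantile normalization and 14.1% with median scaling. Median scaling moved the median difference of all features from 0.03 to -0.17. Without SF1 siRNA replicate 3 the split was 33 higher and 315 lower.

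The leading lower genes did not pass the adjusted threshold and are described by their values. STAR, the cholesterol carrier that feeds mitochondrial steroid synthesis, had the largest difference, -3.75 ± 0.68 (SE of the fit without a block), a 13.5-fold lower level. Its differences were -4.51, -2.74 and -4.00 in pairs 1, 2 and 3, and the SE was 0.39 with the replicate block. SLC40A1, the cellular iron exporter ferroportin, was 2.60-fold lower, with pair differences between -1.58 and -1.14. CILP, a cartilage matrix protein, differed by -2.02 and was well above background on 2 of the 3 SF1 siRNA arrays. SERPINA5, a serine protease inhibitor, was well above background on 0 SF1 siRNA arrays and at least 2.36-fold lower by the processed signal. With normexp its log2 difference was -0.49. CLSTN3, LDB2, LRRC8B, TNFAIP8L3, TSPAN4 and DAB2IP differed by -1.21, -1.05, -0.88, -0.71, -0.67 and -0.59.

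Among the leading higher genes, also not past the adjusted threshold, CTSZ, a lysosomal cysteine protease, was at 3.50 ± 0.35 and 4.50 ± 0.32 (SD, n = 3 each), 2.00-fold higher with SF1 siRNA. ZNF497 and PSKH1 differed by 0.64 and 0.63 at similarly measurable levels. The others were dim. DACH1, a transcriptional repressor, differed by 1.22, PHKG1 by 1.41, SLC45A1 by 0.77, FNDC5 by 0.68, VWA5A by 0.63, SKA3 by 0.62 and HBQ1 by 0.60. CTAGE10P and ASB18 were well above background on 0 non-targeting arrays and were at least 2.07-fold and 1.53-fold higher by the processed signal. With normexp they differed by only 0.28 and 0.21. A second CTAGE10P probe, well above background on 1 array, differed by 0.23 and was lower in 2 of 3 pairs. The leading genes named here other than NR5A1 all kept their sign under the 4 other scalings or sources of values. Median scaling moves all genes by the same small amount, so it could not flip the sign of genes picked as 1.5-fold different. The other 3 use the same arrays from which the genes were picked. Differences stayed within 1.5 times in size for STAR, CLSTN3, LDB2, TSPAN4, DAB2IP, CTSZ, ZNF497 and PSKH1. The others, all dim, were smaller by over 1.5 times with normexp, such as SLC40A1 at -0.87, CILP at -0.66, DACH1 at 0.41, PHKG1 at 0.46 and SLC45A1 at 0.13. Where a leading gene had a second probe that was well above background on all 6 arrays, the sign was the same for CLSTN3, LDB2, LRRC8B, TSPAN4 and, in 2 of 3 pairs, DAB2IP; for ZNF497 the second probe, above background on 5 arrays, had the opposite sign.

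**Figure D1:**
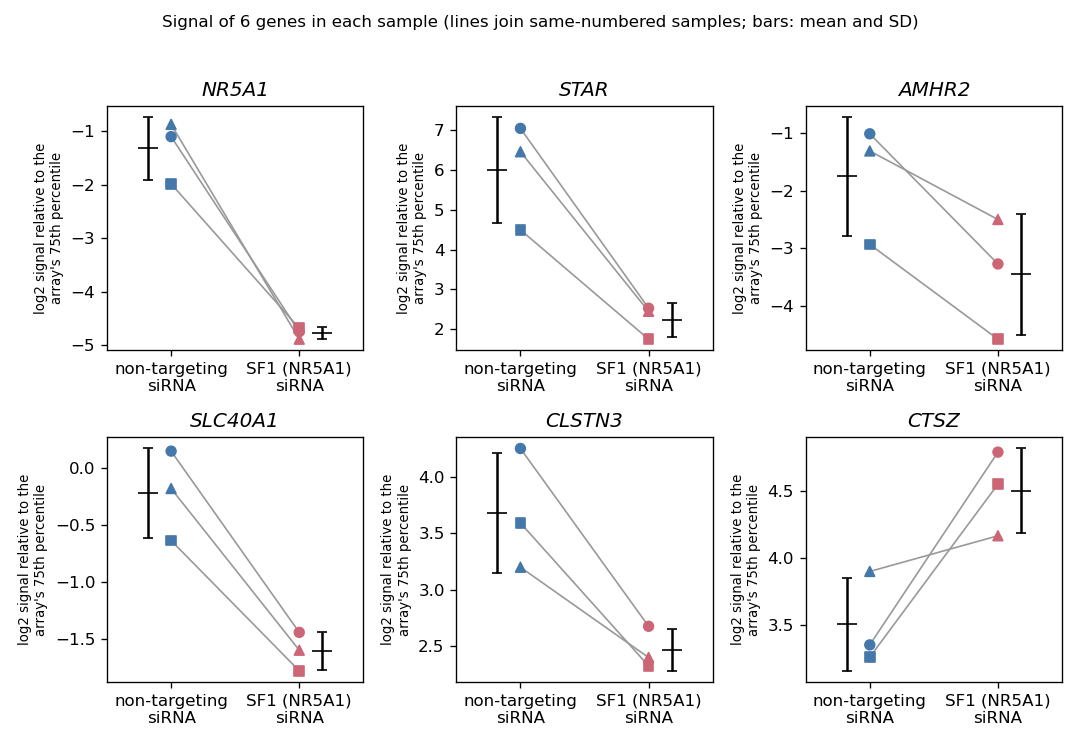
Level of 6 genes in each sample (log2 signal relative to the array's 75th percentile) under non-targeting and SF1 siRNA; lines join same-numbered samples, bars give mean and SD of 3. NR5A1, STAR, AMHR2, SLC40A1 and CLSTN3 were lower and CTSZ was higher in each pair.

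Steroidogenic and ovarian cell genes were the groups with the largest individual differences. Of 11 measured ovarian granulosa, theca and luteal markers, 8 were lower, and the list fell relative to other genes (camera adjusted p = 6.53e-08; adjusted p = 0.956 with an estimated correlation). Adjusted over the list alone 2 members fell, STAR and SERPINA5, and 0 did over all genes tested. With the replicate number as a block the members past the list-alone threshold were STAR, AMHR2 (the receptor of anti-Müllerian hormone, -1.70) and CYP11A1 (the enzyme that starts steroid synthesis from cholesterol, -1.78, a gene outside the naming rule and chosen after its values were seen). SERPINA5 did not pass there. Its computed difference of -2.54 ranged from -4.23 to -0.86 over the pairs and rested on SF1 siRNA signals not well above background. Among members closer to 0 were CYP17A1 at -0.36 and, outside the naming rule, FOXL2 at -0.34 and GATA4 at 0.22. AMHR2 was well above background on 2 of the 3 SF1 siRNA arrays. Of 17 measured steroidogenesis genes and known SF-1 targets, 11 were lower (camera adjusted p = 0.00548; adjusted p = 0.956 with an estimated correlation), and 1 member, STAR, fell when adjusted over the list alone, against 3 with the replicate block (STAR, AMHR2 and CYP11A1). This list shares 5 measured genes with the ovarian one, and its call ended with the replicate block (adjusted p = 0.0839) and when any of 3 single samples was left out (non-targeting replicate 1, SF1 siRNA replicate 2 or 3; adjusted p from 0.116 to 0.539). The list's median was -0.08, and 0.03 without either non-targeting replicate 1 or SF1 siRNA replicate 3.

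Genes of DNA replication and mitosis rose as a list (camera adjusted p = 5.98e-19; adjusted p = 0.956 with an estimated correlation). Of 52 measured members 50 were higher, with a median difference of 0.33, and 45 were higher in all 3 pairs. Median scaling, which moved the median of all features to -0.17, gave a list median of 0.13, and normexp gave 0.21. The list medians were 0.22, 0.40 and 0.34 in pairs 1, 2 and 3. The differences were small: CDK1, the kinase that drives entry into mitosis, differed by 0.53, RRM2, a subunit of ribonucleotide reductase, by 0.75, CCNE2, a cyclin, by 0.72 and MCM2, of the replicative helicase, by 0.37. UHRF1, which maintains DNA methylation during replication and is outside the naming rule, chosen after its values were seen, differed by -0.56 and was lower in each pair. None of the members passed when adjusted over the list alone (0 of 52). Without SF1 siRNA replicate 3, the array with more spots above background, the list's median was 0.30 (camera adjusted p = 4.22e-11). Without non-targeting replicate 2 it was 0.17 (camera adjusted p = 1.68e-04), and over all left-out samples or pairs it lay between 0.17 and 0.47.

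Type I interferon response genes fell as a list by camera (adjusted p = 0.0344, and adjusted p = 0.956 with an estimated correlation). Of 40 members 32 were lower, and the median over all 40 was -0.06. OAS1 differed by -0.28 and USP18 by -0.26, and 0 members passed alone. The list's median was 0.12 without non-targeting replicate 1 and 0.08 without SF1 siRNA replicate 3, and its call ended there, without SF1 siRNA replicate 2 (adjusted p = 0.348), with array weights (adjusted p = 0.749; median -0.01) and under quantile normalization (adjusted p = 0.243), where the median was -0.08. With the replicate block the list passed (adjusted p = 6.02e-05; adjusted p = 0.974 with an estimated correlation), but not without pair 3 (adjusted p = 0.115). Hypoxia and glycolysis genes did not pass (camera adjusted p = 0.260), with 20 of 31 members lower; with the replicate number as a block the list passed (adjusted p = 0.0470; adjusted p = 0.974 with an estimated correlation). The list also passed in some other settings, such as without non-targeting replicate 2 (adjusted p = 2.16e-07), and its median was 0.10 without non-targeting replicate 3 and 0.11 without SF1 siRNA replicate 2. PFKFB3, a regulator of glycolysis, differed by -0.59.

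The other 22 lists did not pass in either fit. Among them, markers of endometrial stromal fibroblasts had a median of 0.07, fibrillar collagens and matrix 0.02, decidualization genes -0.03 (IGFBP3 at -0.77), nuclear receptors of the endometrium -0.01, cholesterol synthesis 0.10, cholesterol efflux 0.08, steroid conversion enzymes 0.08 and the prostaglandin pathway 0.01. Inflammatory cytokines had a median of -0.06, p53 targets 0.03, matrix proteases 0.06, myofibroblast genes 0.04, the unfolded protein response 0.02, the respiratory chain 0.04, ribosomal proteins 0.05, RNA interference genes 0.08 and splicing factors 0.06. Markers of other cell types had medians of 0.08 for epithelial, 0.17 for endothelial, -0.01 for leukocyte, 0.13 for pericyte and 0.07 for mesothelial cells. Some of these 22 lists passed in other settings, such as cholesterol synthesis in 6 of 27 settings and inflammatory cytokines in 4. With array weights cholesterol synthesis had a median of 0.33 (camera adjusted p = 1.21e-04) and inflammatory cytokines -0.46 (camera adjusted p = 1.95e-04).

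**Figure D2:**
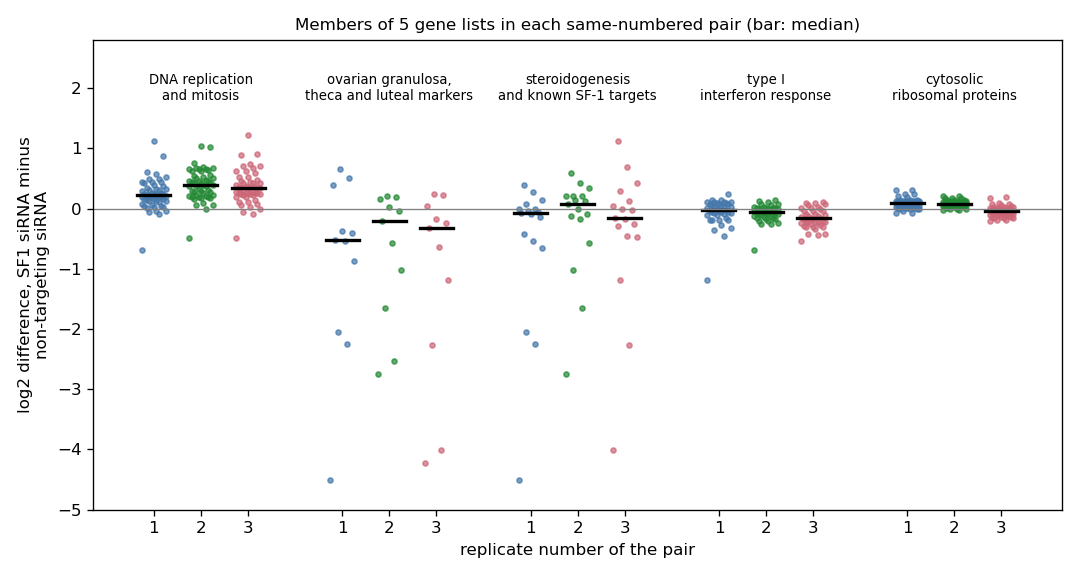
Difference of each member (points) of 5 gene lists in each same-numbered pair, SF1 siRNA minus non-targeting siRNA on the log2 scale, with the list's median as a bar. The DNA replication and mitosis medians were 0.22, 0.40 and 0.34, while a few members of the ovarian and steroidogenesis lists lay far below the rest.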

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

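Normexp on the median signal and the replicate block joined with another choice were chosen after seeing the data; the files lack the mean signal, so normexp on it was not run. Slide and scan could not be blocked, and camera was not run with a random block. Genes past adjusted p 0.05 numbered 0 except 2 with median scaling (NR5A1 and STAR), 6 with the replicate block with trend and robust moderation (among them NR5A1, SLC40A1 and, outside the naming rule, PITPNM3, RIN2 and WIPF3) and 3517 with the deposited value table. That table has differences between numbers removed, so a fit without a block counts too many degrees of freedom; with the block it gave 0. Genes at unadjusted p 0.05 and 1.5-fold, 96 as reported, became 21 with normexp, 370 without the filter, 51 with all 6 arrays above background, 63 with trend and robust moderation, 181 with the value table, 36 at 2-fold, 236 with the replicate block, 281 with a random block, and 171, 195 and 223 with the block joined with the value table, trend and robust moderation, and quantile normalization. Leaving out samples or pairs gave 86 to 532. Lists past the threshold, 4 as reported, became 7 without the filter, 0 with an estimated correlation or fry (with or without the block) and 3 to 7 over left-out samples or pairs.

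NR5A1 stayed lower and past the unadjusted threshold wherever its probe was kept, with computed differences from -3.84 to -0.95 (normexp), and -2.06 with the value table. These rest on SF1 siRNA signals not well above background. The bound of 6.31-fold thus holds for the processed signal only. The filter for all 6 arrays removed NR5A1. Over left-out samples or pairs 20 of 27 list medians changed sign, among them steroidogenesis (-0.17 to 0.03), type I interferon (-0.29 to 0.12), fibrillar collagens (-0.25 to 0.24), ribosomal proteins (-0.11 to 0.17) and myofibroblast genes (-0.21 to 0.27). By test and threshold 5 list results were reversed (3 past the threshold in the other direction, and interferon's 2 not past it). Of the other list results 493 were the same, 146 moved, 29 became stronger and 29 weaker, and some of these also differ in the sign of the median. For named genes 2625 results were the same, 73 moved and 77 became stronger. No named gene passed the adjusted threshold in the reported fit, so none could become weaker. A gene counted as the same thus passed in neither setting. Most of the 77 came from the value table fitted without a block, which counts too many degrees of freedom.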

Other observations

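The lists for histone and iron handling genes, and 1 more that is not reported, were added after seeing the data, and the tests of the left-in array, the scaling, the histone genes and the ovarian markers were chosen after the result was seen. Replication-dependent histone genes, not among the lists fixed in advance, rose as a list (camera adjusted p = 1.47e-08 over the 3 added lists, and adjusted p = 0.346 with an estimated correlation). Of 55 members 48 were higher, and the median over all 55 was 0.18. Iron handling genes, tested because SLC40A1 was among the leading genes, had a median of -0.02 over 24 members, SLC40A1 included (camera adjusted p = 0.0536).

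With 10 splits of the 6 samples no share under 0.05 can be reached. The real split gave 0 genes past adjusted p 0.05 and the highest other 0, so 10 of 10 splits gave as many. At unadjusted p 0.05 and 1.5-fold the real split gave 96 and the highest other 1701, and 8 splits gave as many. For lists the values were 4 and 10, and 8 splits gave as many. The splits that part 1 pair called many times the real count, which points to the structure by replicate number. Among the 4 splits that part all 3 pairs, which differ from the real one by exchanging the 2 samples of a pair, the replicate block gave 236 genes at unadjusted p 0.05 and 1.5-fold for the real one and at most 482 for the others, and 4 lists against at most 9. Camera calls at the preset correlation thus also arose when labels were exchanged within a pair.

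The DNA replication and mitosis list was higher after SF1 siRNA. One array carrying the shift is argued against, since the lower of the medians above the all-gene median in the pairs without SF1 siRNA replicate 3 was 0.21. Subtracting the all-gene median removes any constant shift of an array, so median scaling could not change the list's value above all genes and tests nothing here. Without that subtraction the list's median was 0.13 with median scaling. With quantile normalization the list's median above all genes was 0.27, and with normexp 0.19, the lowest of 5 scalings or sources. The shift thus stayed under these, but other effects that depend on signal level were not tested. Among the 4 splits that part all pairs, 1 (the real one) reached its median of 0.31 relative to all genes, against 0.14 for the highest other, and 4 splits are too few for a share under 0.05. Splits that part only 1 pair reached up to 0.50, so replicate differences move this list by as much. A hypothesis of more cells replicating DNA stays open: the histone genes' median lay 0.15 above all genes, but at -0.05 in pair 1.

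STAR, AMHR2 and CYP11A1 were lower in each pair, while 6 of 17 members of the steroidogenesis list were higher and its call was lost in several settings. A dependence of these 3 genes on steroidogenic factor 1 was not tested beyond this siRNA, and fewer ovarian steroidogenic cells in those cultures may give lower values too. The 6 ovarian markers outside the SF-1 target list had a median of -0.25. Of these, 5 lay within 1 of no difference and SERPINA5, not well above background after SF1 siRNA, was at least 2.36-fold lower by the processed signal. The markers thus leave both readings open.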
